A study of Mus musculus with 12 samples.

How the data were processed

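RNA sequencing of MODE-K cells, a mouse small-intestinal epithelial line, gave 12 libraries in 4 groups of 3: control (0 Gy, 0 h), 4 Gy at 48 h, 12 Gy at 24 h and 12 Gy at 48 h. Groups and replicate numbers were taken from the labels. Per the labels, adapters were trimmed with cutadapt 1.9 and reads were checked with FastQC, whose version is not stated, and libraries followed an Illumina protocol. The deposited table names assembled loci in a style used for long-read data, and which platform gave the reads is not settled by the sources used here. The aligner, the genome build, the annotation and the strandedness of counting are not given in the sources used here.

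The deposited gene table holds read counts per gene and library, whole numbers without normalization. It also holds CPM, which the authors computed as the count over the column total; recomputed here, these differed by at most 4.78e-06. The table further holds other values, the adjusted p and log2 fold change of the authors' own DESeq2 comparisons, whose version and filter are not stated. These were not used in the tests here. At the authors' adjusted p under 0.01 with a fold of at least 1.5, their table called 754 genes higher and 1427 lower at 12Gy_48h, 1284 and 3389 at 12Gy_24h and 158 and 707 at 4Gy_48h against control. For 48 h against 24 h after 12 Gy it called 1094 higher and 857 lower, and for 12 Gy against 4 Gy at 48 h 136 higher and 93 lower. The table had 33636 lines, of which 11 were the overflow of a long annotation cell and held 0 counts. Of the 33625 genes left, 26299 had reads in some library. Symbols were restored by Ensembl identifier (22022 of 22036 matched), since 27 had been turned into dates. Gene positions come from the GENCODE mouse annotation of GRCm38.

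Counts were fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling and a quasi-likelihood fit with 1 mean per group over all 12 libraries. There were 5 comparisons: each irradiated group against control, 12Gy_48h against 12Gy_24h, and 12Gy_48h against 4Gy_48h. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that comparison. The filter kept 15086 genes. The biological coefficient of variation was 0.144. Library totals ran from 3616416 to 4831641 assigned reads. The gene test was tested on simulated data in 10 draws of changed genes. For 12Gy_48h against control it recovered 13.5% of 1.5-fold, 50.2% of 2-fold (34.8 to 57.5% over the draws) and 88.6% of 4-fold changes, with 5 to 13 false calls among 15086 genes. For 12 Gy against 4 Gy at 48 h it recovered 48.1% of 2-fold changes. Each draw changed a small set of genes, up or down at random. The data had many more calls, largely one-sided among the new loci, so recovery and false calls there may differ. Intervals and floors cover counting error only. For genes with 0 reads in a group, folds were computed against a floor of 3 counts over the group, and for genes with 1 to 3 reads a ratio is given with its 95% counting interval.

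There were 25 gene lists, fixed from general knowledge of radiation responses and cell types: p53 targets, pyroptosis, necroptosis, intrinsic apoptosis, ferroptosis, G1/S and DNA replication, G2/M and mitosis, homologous recombination and Fanconi, end joining, interferon-stimulated, cytosolic nucleic acid sensing, NF-kB and secretory phenotype, MHC class I presentation, cholesterol synthesis, unfolded protein and integrated stress response, antioxidant response, hypoxia and glycolysis, YAP targets, epithelial, intestinal lineage, fibroblast and mesenchymal, immune cell, endothelial, mitochondrially encoded and ribosomal protein genes. Each was tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. The intestinal lineage list had too few expressed genes to test, so 24 lists were tested. Camera compares a list with the other tested genes, so its direction can differ from the sign of the median. Lists share members: Zbp1, for example, is in the pyroptosis, necroptosis, interferon and sensing lists.

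Genes to name were set by rule: in each comparison with control the 8 largest rises and 8 largest falls, and 5 each in the other comparisons, among genes past adjusted p 0.05 whose 3 values in each group did not overlap and whose mean was at least 1 CPM in the higher group, without predicted or unnamed loci. The rule added up to 4 called members of each list by adjusted p, every tested pyroptosis gene, and Cdkn1a, Mdm2, Gsdmd, Gsdme, Casp1 and Trp53 in every comparison. Some genes that the rule names are not reported here. The comparisons, tests, lists, naming rule and alternatives were written before the data were examined, except the fits to known genes alone, which were added after the fall of the new loci had been seen. Means ± SD of single genes are CPM after TMM scaling.

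Alternatives were no filter, a mean of at least 5 CPM in some group, RLE scaling (the DESeq2 size factors), upper-quartile scaling, DESeq2 1.42.0, only the 6 libraries compared, the replicate number as a block, a fold of at least 2, each library left out, camera with an estimated correlation, and fry. Shared calls were set beside the product of the call rates and beside 20 simulations. In each, counts of all 12 libraries were drawn around the control means with no gene changed, and the irradiated groups shared the 3 simulated controls. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Raw reads were not analysed here.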

Results

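RNA was sequenced from MODE-K cells, an epithelial line derived from mouse small intestine, with and without exposure to gamma rays from a cobalt source. The 12 libraries fell into 4 groups of 3: unirradiated cells taken at 0 h (control), cells taken 48 h after 4 Gy (4Gy_48h), and cells taken 24 h or 48 h after 12 Gy (12Gy_24h and 12Gy_48h). Library totals were 4831641, 3776038 and 3779351 reads in the controls, 3924144, 4026800 and 3748891 at 4Gy_48h, 3953638, 3831703 and 3782391 at 12Gy_24h, and 3628034, 3724835 and 3616416 at 12Gy_48h. The series title concerns pyroptosis, a lytic form of cell death in which inflammatory caspases cut gasdermins and the fragments open pores in the plasma membrane. The labels speak of 3 parallel groups per dose but do not say that these were separate cultures, so each p measures the spread between these libraries, which may be technical. Controls were taken at 0 h, so dose and time in culture cannot be separated in the comparisons with control. Whether reads were counted by strand is not stated, which leaves the counts of overlapping genes such as Ankrd37 with Ufsp2, Avil with Tsfm, Tap1 with Psmb9, Ripk1 with Serpinb6a, Xrcc6 with Desi1, Bid with Bcl2l13, S100a4 with Gm42674 and Trex1 with Atrip uncertain. The share of reads between close relatives, such as Ifit3 and Ifit3b, the H2 and Oas genes, Gsta1 and Tgtp1, is uncertain too.

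The deposited gene table held 33625 genes, of which 10995 were loci without an Ensembl gene (new loci, assembled by the authors). Of 15086 genes tested, 9809 were known genes, 4898 were new loci and 379 were long noncoding loci. New loci took 21.0 ± 1.03% of the reads in the controls, 15.8 ± 0.947% at 4Gy_48h, 11.9 ± 0.0571% at 12Gy_24h and 14.7 ± 0.606% at 12Gy_48h (SD, n = 3). Most of these loci had negative log2 fold changes, with medians of -0.906 at 12Gy_48h, -1.871 at 12Gy_24h and -0.695 at 4Gy_48h, where 37.4% were called lower. Scaling over all genes therefore moved the median log2 fold change of the known genes up, to 0.195 at 12Gy_48h, 0.233 at 12Gy_24h and 0.137 at 4Gy_48h. With the known genes scaled and tested alone these medians were 0.009, -0.002 and -0.011. Fold changes of single genes below come from the fit to all genes and are to be read against those shifts. Known genes named as having risen or fallen also passed with known genes alone and with each library left out, unless a value says otherwise. That is not a trait of all genes named by the rule. Of those called, 63 of 87 at 12Gy_48h, 75 of 104 at 12Gy_24h and 21 of 60 at 4Gy_48h passed both checks. For 48 h against 24 h 67 of 88 did, and for 12 Gy against 4 Gy 16 of 47. Fold changes are on the log2 scale, adjusted p values for genes are from edgeR and those for gene lists are from limma camera. Where a single count of called list members is given, the count adjusted over the list alone was the same.

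**Figure D1:**
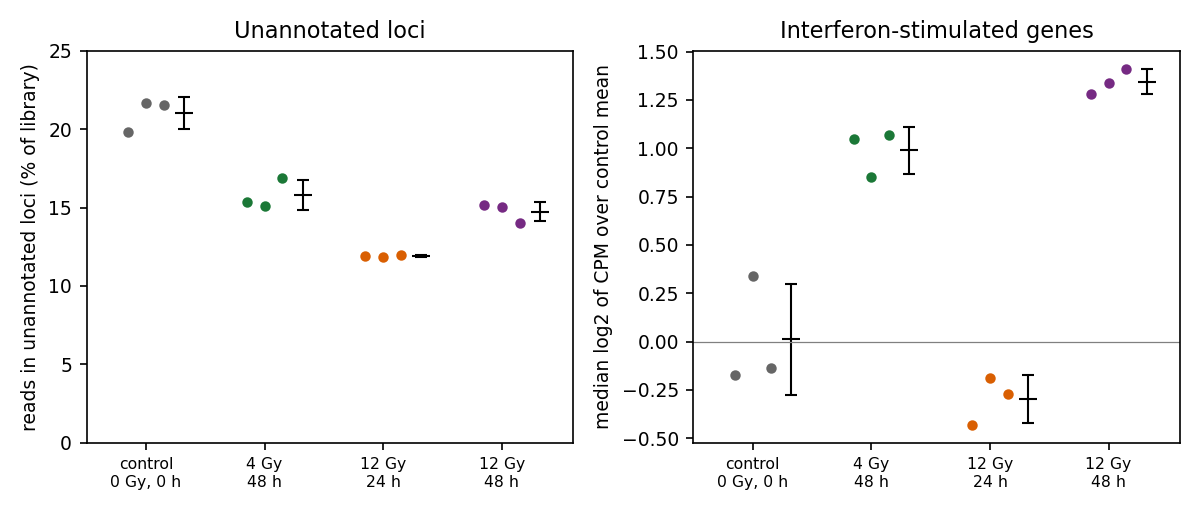
Left, percent of each library's reads in loci without an Ensembl gene; right, the median log2 ratio of the interferon-stimulated genes over the control mean in each library. Points are libraries and bars are the mean ± SD of 3; the interferon medians ran from 1.283 to 1.412 at 12Gy_48h and from -0.431 to -0.189 at 12Gy_24h.

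Cells taken 48 h after 12 Gy were compared with control to see which transcripts differed 2 days after the higher dose. The largest coordinated rise was in interferon-stimulated genes, which encode antiviral effectors and their sensors. Ifit3, Ifit3b and Rsad2 rose by 3.92, 3.61 and 3.59, and Oasl1 rose by 1.81. Zbp1, which encodes a sensor of Z-form nucleic acid able to start pyroptosis and necroptosis, rose from 8.37 ± 1.68 to 67.9 ± 10.0 CPM after scaling (SD, n = 3), a log2 fold change of 3.01 with an adjusted p of 7.29e-07. Complement factor Cfb rose by 3.68, the surface protein gene Ly6a by 3.49, and the chemokine genes Ccl5 and Cxcl10 by 2.46 and 1.98. Class I antigen presentation rose with them: H2-K1 by 1.02, the peptide-loading gene Tapbp by 1.69 and the immunoproteasome gene Psmb8 by 1.59. Nucleic acid sensing genes rose as well, among them Trex1 (1.67), Adar (1.00) and Samhd1 (0.81).

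Genes of the antioxidant response, which follow the transcription factor NRF2, rose at the same time: Gsta1 by 2.92, Nqo1 by 2.07, Gsta4 by 1.96, Hmox1 by 1.61 and Pgd by 1.00. The iron storage gene Ftl1 rose by 0.81, and the endoplasmic reticulum chaperone genes Calr, Creld2 and Sdf2l1 rose by 0.80, 0.99 and 1.03. Among the falls were the protease inhibitor gene Timp1 (-1.04), the glutathione-degrading enzyme gene Chac1 (-1.06) and the end joining gene Xrcc6 (-0.65). The largest falls under the naming rule were in sparsely expressed genes such as Cdsn (-1.70), Bpifc (-1.78) and Wdr63 (-1.68). Usp50 had 158 reads at 12Gy_48h and 0 in the controls, at least 59.5-fold higher against a floor of 3 counts over the group, but how reads were shared among gene models is not given. Prl2c2 and Hbb-bh1 were 20.3 times (95% counting interval 5.23 to 174) and 19.8 times (5.08 to 170) higher from 2 reads each in the controls. Cdkn1a, the p53-driven cell cycle inhibitor gene, did not pass (-0.07, adjusted p = 0.741). Mdm2, whose product restrains p53, rose by 0.53 (adjusted p = 0.00721), a call lost with known genes alone (adjusted p = 0.103). Trp53 itself did not pass (-0.23, adjusted p = 0.198) but was lower with known genes alone (-0.41, adjusted p = 0.0398).

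For pyroptosis, 17 of the 37 genes listed beforehand could be tested. Zbp1, Casp1, Ninj1 and Dpp9 rose. Casp1, the inflammatory caspase gene, went from 14.9 ± 2.70 to 27.2 ± 2.36 CPM (SD, n = 3; log2 fold change 0.87, adjusted p = 0.000751). Ninj1, whose product ruptures the membrane after pores form, rose by 0.47 and Dpp9, which encodes an inhibitor of the NLRP1 inflammasome, by 0.44. Neither passed with known genes alone (adjusted p = 0.171 and 0.235). Ninj1 also lost its call without 12Gy_48h replicates 1 and 2 and control replicate 3 (adjusted p = 0.056, 0.0825 and 0.053), and Dpp9 without 12Gy_48h replicates 1 and 2 and control replicate 2 (0.062, 0.0892 and 0.0588). The pore-forming genes Gsdmd (0.40, adjusted p = 0.509) and Gsdme (0.47, adjusted p = 0.200) did not pass, nor did Casp4 (0.48) or Txnip (-0.05). Gsdmd had 4 to 21 reads per library, Pycard and Il1b 0 to 1, Nlrp3 0 to 10 and Il18 0 to 20. On the GRCm38 annotation Zbp1 lies on chromosome 2 at 173206612 to 173218923, Casp1 on chromosome 9 at 5298517 to 5307265, Gsdmd on chromosome 15 at 75862327 to 75867408 and Gsdme on chromosome 6 at 50188888 to 50263862, matched by Ensembl identifier because the authors' build is not given.

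**Figure D2:**
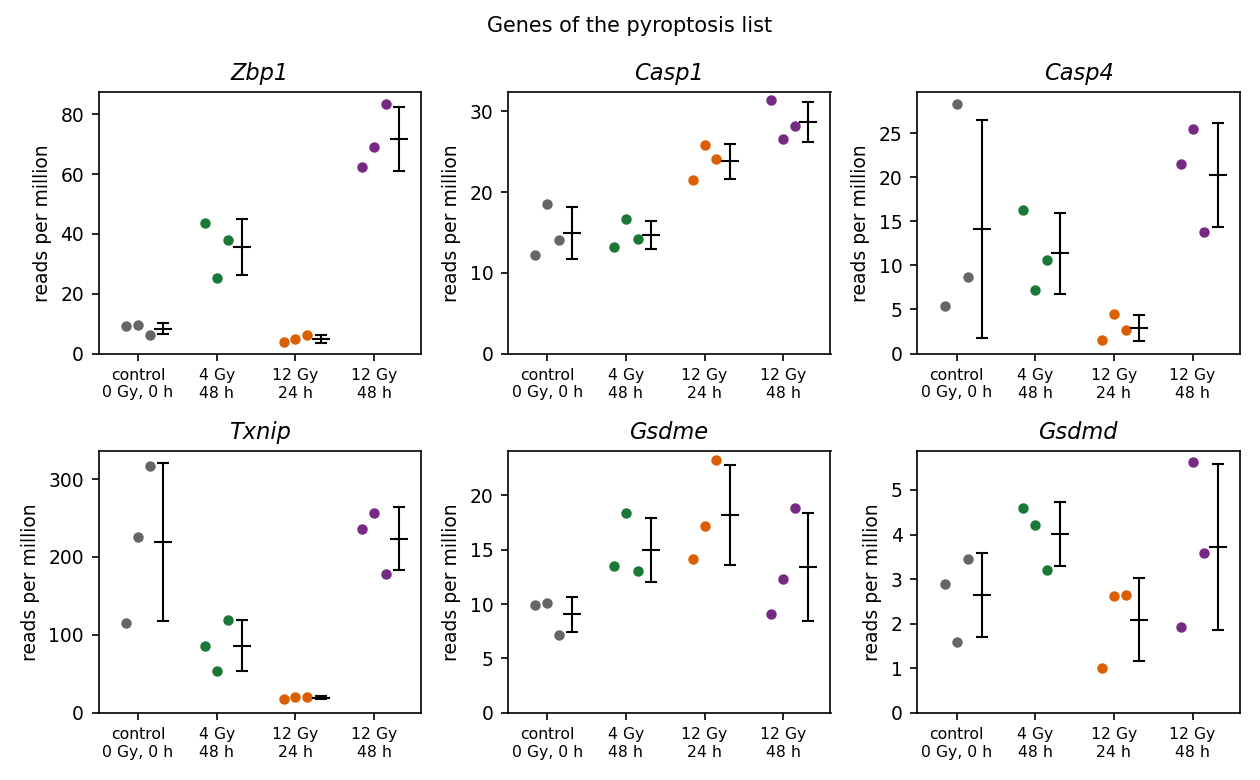
CPM over the library total, without TMM scaling, for 6 genes of the pyroptosis list in the 4 groups. Points are libraries and bars are the mean ± SD of 3; Zbp1 was highest at 12Gy_48h and Txnip lowest at 12Gy_24h.

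Of 24 gene lists fixed beforehand and tested at 12Gy_48h, 7 passed with known genes alone, 5 higher and 2 lower. Over all tested genes 11 passed, all higher. That background included the new loci, most of which had negative log2 fold changes, which moves lists of known genes towards higher. Interferon-stimulated genes led: 44 of 45 were called higher (44 adjusted over the list alone), with a median of 1.38 and an adjusted p of 8.04e-46. Antioxidant response genes (17 of 21 higher, 18 over the list alone, median 0.64, adjusted p = 2.12e-10), class I presentation genes (12 of 17, 14 over the list alone, median 0.74, adjusted p = 2.91e-09) and nucleic acid sensing genes (7 of 15, 8 over the list alone, median 0.56, adjusted p = 3.59e-06) followed. These 4 lists alone kept their calls with an estimated correlation, each at an adjusted p of 0.0402. The interferon list shares Tap1, Psmb8 and Psmb9 with class I genes, and Zbp1, Ddx58, Ifih1 and Samhd1 with sensing genes. The calls of these lists are thus not independent, and no list was tested without its shared members. In the fit to known genes alone with an estimated correlation only interferon-stimulated genes passed (0.0245), while antioxidant, class I and sensing genes stood at 0.0583, 0.0584 and 0.0584. Hypoxia and glycolysis genes passed with 10 of 21 higher (10 over the list alone; median 0.52, adjusted p = 0.000328; adjusted p = 0.151 with an estimated correlation). Ferroptosis genes had 9 higher and 2 lower of 19 (10 and 2 over the list alone; median 0.44, adjusted p = 0.00176; adjusted p = 0.142 with an estimated correlation). Unfolded protein and integrated stress response genes had 14 higher and 3 lower of 27, over the list alone too (median 0.42, adjusted p = 0.00176; adjusted p = 0.189 with an estimated correlation). Pyroptosis genes had 4 of 17 higher by either adjustment (median 0.40, adjusted p = 0.00406; adjusted p = 0.0509 with an estimated correlation), and the median was 0.24 without 12Gy_48h replicate 2. Fibroblast and mesenchymal markers had 8 of 14 higher by either adjustment (median 0.41, adjusted p = 0.00888; adjusted p = 0.142 with an estimated correlation).

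Necroptosis and mitosis genes passed narrowly in that comparison. Necroptosis genes had 4 of 13 higher by either adjustment (median 0.21, adjusted p = 0.0267; adjusted p = 0.111 with an estimated correlation), with medians of 0.12 without control replicate 1 and 0.08 without 12Gy_48h replicate 3. G2/M and mitosis genes had 4 higher and 1 lower of 38 (2 and 1 over the list alone; median 0.20, adjusted p = 0.037; adjusted p = 0.622 with an estimated correlation). That call ended without control replicates 2 and 3 and 12Gy_48h replicate 3 (adjusted p = 0.0646, 0.159 and 0.27), and the median was 0.33 without control replicate 1. With known genes alone, pyroptosis, ferroptosis, stress response, fibroblast, necroptosis and mitosis genes did not pass (adjusted p = 0.0733, 0.0768, 0.261, 0.0974, 0.299 and 0.976), whereas G1/S and DNA replication genes (median -0.41, adjusted p = 3.53e-05) and ribosomal protein genes (median -0.34, adjusted p = 1.2e-11) fell. Both falls were lost there with an estimated correlation (adjusted p = 0.443 and 0.1), and read-weighted transcript length was 1080.7 ± 3.07 nt at 12Gy_48h against 1040.9 ± 18.0 nt in the controls (SD, n = 3). In the fit to all genes G1/S and ribosomal protein genes did not pass (medians -0.22 and -0.15, adjusted p = 0.469 and 0.18), with 3 of 36 and 9 of 30 genes lower (2 over the list alone for the first) and 1 ribosomal gene higher. Lists not passed were p53 targets (median 0.20, adjusted p = 0.105, but 0.0295 without control replicate 3), intrinsic apoptosis (0.158), end joining (0.469), cholesterol synthesis (0.18), immune cell (0.207), endothelial (0.212) and mitochondrially encoded genes (0.611). NF-kB and secretory genes (0.0998, but 0.00463 without control replicate 2), YAP targets (0.0582, but 0.0397 without control replicate 1 and 0.0218 without 12Gy_48h replicate 1) and epithelial genes (0.105, but 0.0471 without control replicate 1) did not pass either. Homologous recombination and Fanconi genes had a test direction of higher (adjusted p = 0.991) against a median of -0.03 and a mean of -0.10.

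At 12Gy_48h, 4995 genes passed, 1945 higher and 3050 lower. Among the known genes 1790 were higher and 367 lower, and among the new loci 122 were higher and 2611 lower. Known genes tested alone gave 1453, 664 higher and 789 lower, so the balance of calls by direction among known genes depended on the scaling. Their median log2 fold change moved from 0.195 to 0.009. Without 12Gy_48h replicate 2, 1269 genes were higher and 2534 lower, and with DESeq2 1281 and 2648.

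Cells taken 24 h after 12 Gy were compared with control to describe the first day after the higher dose. At this time Aldoa, Pgk1, Tpi1 and Pfkl, which encode glycolytic enzymes, rose by 1.36, 1.14, 1.10 and 1.49. Tfrc, the transferrin receptor gene, rose by 2.53, and the ferritin genes Fth1 and Ftl1 rose by 1.15 and 0.57. The antioxidant genes Nqo1, Hmox1, Gsta4 and Pgd rose by 2.31, 2.25, 1.62 and 1.12. Krt18, Vim, S100a4 and Sparc rose by 2.14, 1.86, 1.64 and 1.16. The YAP-responsive genes Wwc1 and Ankrd1 rose by 1.80 and 1.18.

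Interferon-stimulated genes did not rise at 24 h: Usp18, Ifi44, Oas1g and Dhx58 fell, with log2 fold changes of -1.14, -1.12, -1.11 and -1.44, and Zbp1 did not pass (-0.67, adjusted p = 0.0741), though it did with known genes alone (-0.91, adjusted p = 0.0486). Several p53 targets fell, including Fas (-1.95), Pidd1 (-1.45) and Mdm2 (-0.61, adjusted p = 0.0018). Cdkn1a (-0.10, adjusted p = 0.564) and Trp53 (-0.30, adjusted p = 0.0765) did not pass, but Trp53 did with known genes alone (-0.53, adjusted p = 0.0102). Lcn2, an iron-binding defence protein gene, fell by 6.85, from widely spread control values (111 ± 129 CPM, SD, n = 3). The casein gene Csn3 fell by 3.78, and Avil and Tenm4 by 3.81 and 3.51. The chemokine gene Cxcl1 fell by 3.46 (adjusted p = 0.0145), but without control replicate 2 the change was -0.83 (adjusted p = 0.483). Among sparse genes Mfap3l and Dpys rose by 3.14 and 3.46. Il24, Hbb-bh1 and Ccr1 were 27.3 times (95% counting interval 7.18 to 232), 26.2 times (6.89 to 223) and 17.8 times (5.77 to 89.5) higher from 2, 2 and 3 control reads. Taf7l, Tmem86a and Prss57 were 23 times (7.58 to 114), 25.2 times (4.16 to 1030) and 18.7 times (2.99 to 774) lower. Usp50 had 280 reads against 0, at least 99.9-fold higher.

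Within the pyroptosis list, Txnip, whose product activates the NLRP3 inflammasome, fell from 220 ± 101 to 20.6 ± 2.18 CPM (SD, n = 3; log2 fold change -3.41, adjusted p = 4.35e-07). Gsdme rose from 9.09 ± 1.64 to 19.6 ± 5.54 (1.09, adjusted p = 0.00263) and Casp1 from 14.9 ± 2.70 to 25.5 ± 2.54 (0.77, adjusted p = 0.000955). Casp4 fell (-2.16, adjusted p = 0.00456), with a value of -1.21 without control replicate 2 (adjusted p = 0.0482). Dpp8 rose by 0.62 but did not pass with known genes alone (adjusted p = 0.101). Nek7 rose by 0.54 (adjusted p = 0.0222), which was lost with known genes alone (0.264) and without control replicate 1 (0.0958) or 12Gy_24h replicate 1 (0.0609). Gsdmd did not pass (-0.27, adjusted p = 0.673). As a list these genes did not pass (5 of 17 higher and 2 lower by either adjustment, adjusted p = 0.244), and the test and median (0.23) pointed up while the mean was -0.11.

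With known genes alone, without the falling new loci as background, 7 lists passed at 24 h, 4 higher and 3 lower. Over all tested genes 9 lists passed, all higher, and none kept its call with an estimated correlation. Hypoxia and glycolysis genes led with 19 of 21 higher by either adjustment (median 0.98, adjusted p = 1.88e-09; adjusted p = 0.0933 with an estimated correlation), then antioxidant genes with 19 of 21 higher (20 over the list alone; median 0.80, adjusted p = 9.27e-09; adjusted p = 0.0933 with an estimated correlation). With known genes alone both passed also with an estimated correlation (adjusted p = 0.0413 each). Ferroptosis genes had 10 of 19 higher (median 0.42, adjusted p = 5.17e-05; adjusted p = 0.124 with an estimated correlation) and fibroblast and mesenchymal markers 7 higher and 1 lower of 14 (median 0.60, adjusted p = 0.00389; adjusted p = 0.168 with an estimated correlation). YAP targets had 6 higher and 1 lower of 15 (7 and 1 over the list alone; median 0.27, adjusted p = 0.0357; adjusted p = 0.335 with an estimated correlation), a call lost without control replicate 2 (0.0609). Epithelial genes had 2 higher and 1 lower of 8 (median 0.49, adjusted p = 0.0426; adjusted p = 0.34 with an estimated correlation), lost without control replicate 2 (0.0757) or 12Gy_24h replicate 2 (0.0548). Mitochondrially encoded genes had 5 of 12 higher (median 0.47, adjusted p = 0.0426; adjusted p = 0.431 with an estimated correlation), lost without control replicates 1 and 2 (0.0835 and 0.0609) or 12Gy_24h replicate 1 (0.0814).

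Mitosis and ribosomal protein genes changed sign with the scaling at 24 h. G2/M and mitosis genes had 10 higher and 3 lower of 38 and a median of 0.21 (adjusted p = 0.0309; adjusted p = 0.654 with an estimated correlation), but -0.02 with known genes alone (adjusted p = 0.971). Their call ended without control replicates 2 and 3 (adjusted p = 0.0542 and 0.0706), and the median rose to 0.44 without control replicate 1 and to 0.33, 0.35 and 0.34 without 12Gy_24h replicates 1, 2 and 3. Ribosomal protein genes had 9 higher and 1 lower of 30 (7 and 1 over the list alone) and a median of 0.14 (adjusted p = 0.0309; adjusted p = 0.465 with an estimated correlation), but -0.09 with known genes alone (adjusted p = 0.132). They did not pass without control replicate 2 (adjusted p = 0.0659), and the medians were 0.23 and 0.25 without 12Gy_24h replicates 1 and 2. YAP, epithelial and mitochondrially encoded genes did not pass with known genes alone (adjusted p = 0.384, 0.107 and 0.188). P53 targets had 1 higher and 11 lower of 33 (1 and 9 over the list alone; median -0.28, adjusted p = 0.608), and interferon-stimulated genes 3 higher and 16 lower of 45 (2 and 16 over the list alone; median -0.30, adjusted p = 0.476). Both fell with known genes alone (medians -0.52 and -0.54, adjusted p = 1.58e-08 and 2.53e-10), but not with an estimated correlation as well (0.156 and 0.325). Class I presentation genes had 3 higher and 4 lower of 17, and their test pointed up (adjusted p = 0.879) against a median of -0.29 and a mean of -0.24; with known genes alone they fell (median -0.53, adjusted p = 0.000931), which was lost with an estimated correlation (0.325).

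Lists not passed at 24 h were necroptosis (adjusted p = 0.136), homologous recombination (0.235), end joining (0.279), nucleic acid sensing (0.126), stress response (0.17), immune cell (0.608) and endothelial genes (0.316). NF-kB and secretory genes (0.476) had a test direction of higher against a median of -0.01 and a mean of -0.25. Intrinsic apoptosis genes, 9 higher and 1 lower of 20, stood at 0.0546 and passed with RLE scaling (0.0489) and without control replicate 3 (0.0465) or 12Gy_24h replicate 1 (0.035) or 2 (0.0386). G1/S genes stood at 0.108 and passed without control replicate 1 (0.0228) or 12Gy_24h replicate 2 (0.0474). Cholesterol synthesis genes stood at 0.0738 and passed without 12Gy_24h replicate 1 (0.035). In all, 7238 genes passed at 12Gy_24h, 2798 higher and 4440 lower. Known genes gave 2600 higher and 391 lower, and new loci 135 higher and 3954 lower, which was 80.7% of those tested. With known genes alone 1673 passed, 898 higher and 775 lower.

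**Figure D3:**
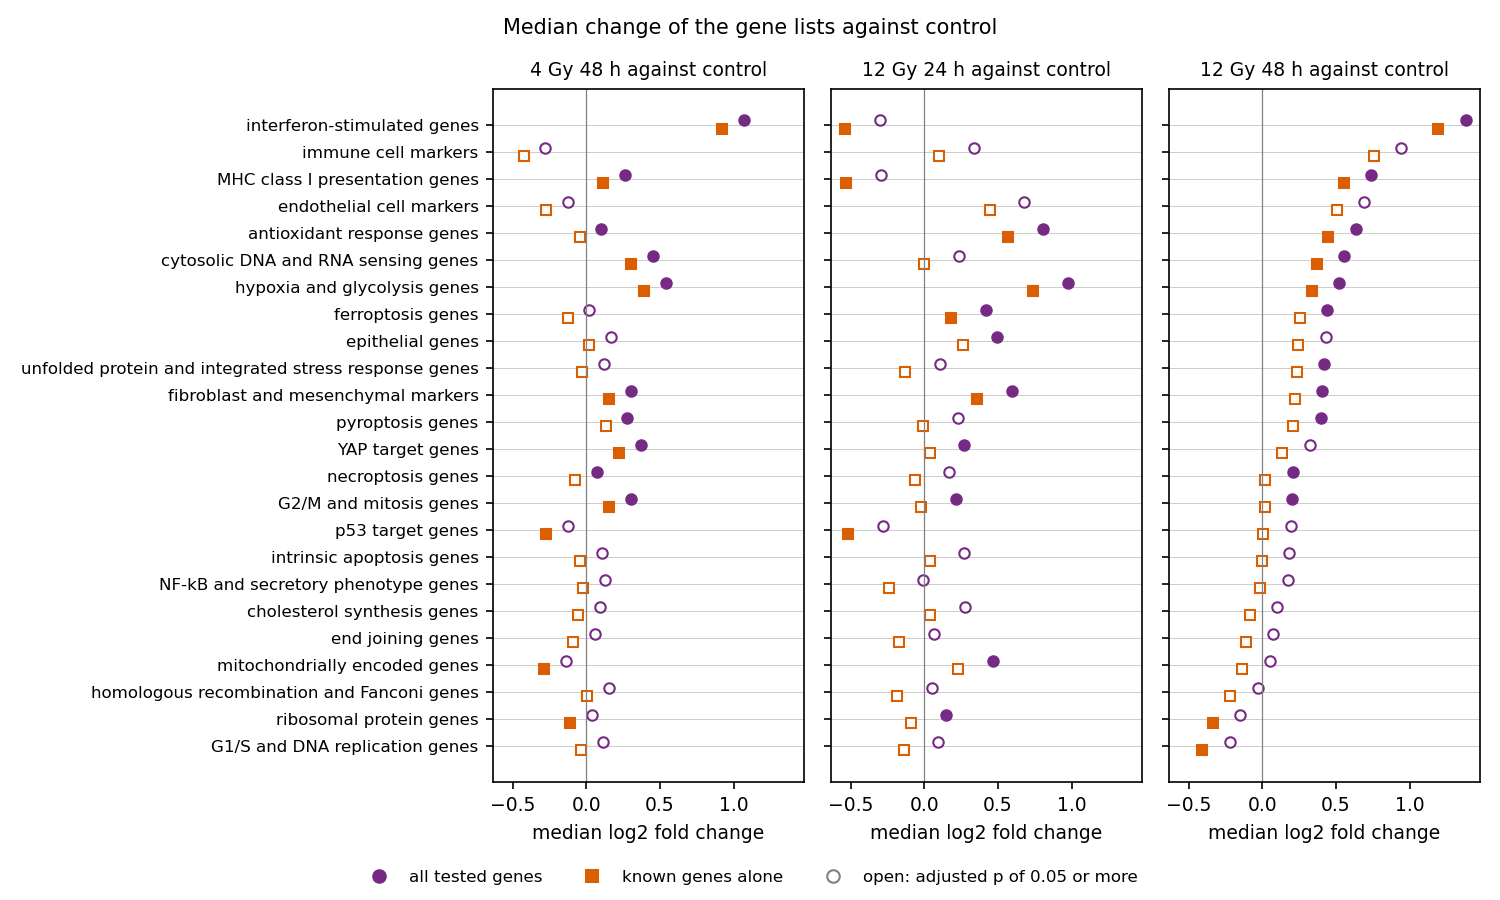
Median log2 fold change of 24 gene lists in the 3 comparisons with control, from all tested genes (circles) and from known genes scaled and tested alone (squares); filled symbols have a limma camera adjusted p under 0.05. At 12Gy_24h the medians of mitosis and ribosomal protein genes were 0.21 and 0.14 over all genes and -0.02 and -0.09 with known genes alone.

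Cells taken 48 h after 4 Gy were compared with control to describe the lower dose at the later time. Interferon-stimulated genes again led: Ifit3, Cmpk2, Rsad2 and Bst2 rose by 2.61, 2.43, 2.23 and 1.11. Tgtp1, an interferon-induced GTPase gene, rose by 2.29. Zbp1 rose from 8.37 ± 1.68 to 36.1 ± 9.86 CPM (SD, n = 3; log2 fold change 2.09, adjusted p = 4.55e-05). The RNA sensor gene Ddx58 and the RNA editing gene Adar rose by 0.83 and 0.81. Ankrd37, a hypoxia-responsive gene, rose by 3.11, and the glycolytic enzyme genes Pfkl, Aldoa and Pgam1 by 0.93, 0.74 and 0.57. The mesenchymal genes S100a4 and Sparc rose by 1.19 and 0.62, and the cytokinesis gene Anln by 0.84. Txnip fell from 220 ± 101 to 87.2 ± 33.1 CPM (-1.33, adjusted p = 0.00483), as did Avil (-2.06) and the axon guidance receptor gene Robo3 (-1.66).

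Members of the pyroptosis list that did not pass at 4Gy_48h included Casp1 (-0.01, adjusted p = 0.984), Gsdmd (0.59, adjusted p = 0.367) and Gsdme (0.72, adjusted p = 0.0755). P53 pathway genes did not rise. Cdkn1a (-0.26, adjusted p = 0.208) and Mdm2 (-0.32, adjusted p = 0.121) did not pass, and Trp53 fell (-0.43, adjusted p = 0.0326). That call ended without control replicates 1, 2 and 3 (adjusted p = 0.0558, 0.0723 and 0.0871) and without 4Gy_48h replicates 1, 2 and 3 (0.0554, 0.124 and 0.0622). The p53 target Btg2 fell by 1.23, and without control replicate 3 by 0.83 (adjusted p = 0.0543). Sh2d6 fell by 1.82, and without 4Gy_48h replicate 3 by 2.78. Usp50 had 227 reads against 0, at least 80.1-fold higher. The transcripts of a second Nnt identifier and of Pcdhgb7, which share sequence with neighbouring gene models, were at least 15.9-fold higher and at least 19.5-fold lower, calls lost with known genes alone (adjusted p = 0.125 and 0.0898). The Nnt call also ended without control replicates 1, 2 and 3 (adjusted p = 0.0638, 0.0696 and 0.0689) or 4Gy_48h replicates 2 and 3 (0.0726 and 0.0697), and the Pcdhgb7 call without control replicate 3 (0.0962) or 4Gy_48h replicates 1 and 2 (0.0735 and 0.0788).

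With known genes alone, without the falling new loci as background, 10 lists passed at 4Gy_48h, 7 higher and 3 lower. Over all tested genes 10 lists passed as well, all higher. Interferon-stimulated genes had 40 of 45 higher (42 higher and 1 lower over the list alone; median 1.07, adjusted p = 1.31e-41), and hypoxia and glycolysis genes 14 of 21 (17 over the list alone; median 0.54, adjusted p = 1.35e-11). Only these lists kept their calls with an estimated correlation, each at an adjusted p of 0.0468. Nucleic acid sensing genes had 6 of 15 higher (median 0.45, adjusted p = 7.76e-06; adjusted p = 0.052 with an estimated correlation), class I presentation genes 5 of 17 (median 0.26, adjusted p = 0.000233; adjusted p = 0.163 with an estimated correlation) and YAP targets 3 of 15 (4 over the list alone; median 0.37, adjusted p = 0.00322; adjusted p = 0.163 with an estimated correlation). Fibroblast and mesenchymal markers had 4 of 14 higher (median 0.30, 0.46 without control replicate 3; adjusted p = 0.00322; adjusted p = 0.142 with an estimated correlation). G2/M and mitosis genes had 4 of 38 higher (1 over the list alone; median 0.30, 0.49 without control replicate 1; adjusted p = 8.17e-05; adjusted p = 0.506 with an estimated correlation). Pyroptosis genes had 1 higher and 1 lower of 17 (median 0.28, adjusted p = 0.0223; adjusted p = 0.142 with an estimated correlation), which ended without control replicate 1 (0.114).

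Antioxidant and necroptosis genes passed at 4Gy_48h with small medians. Antioxidant genes had 2 of 21 higher (median 0.10, adjusted p = 0.0173; adjusted p = 0.367 with an estimated correlation). The call ended without control replicate 3 (0.053) or 4Gy_48h replicate 1 (0.0948), and the medians were 0.30 without control replicate 2 and 0.19 and 0.16 without 4Gy_48h replicates 2 and 3. Necroptosis genes had 1 of 13 higher (median 0.07, adjusted p = 0.0477; adjusted p = 0.156 with an estimated correlation). Their call ended without control replicates 1 and 3 (0.0817 and 0.053) and 4Gy_48h replicates 1 and 3 (0.0698 and 0.103), and the medians were 0.14 and 0.16 without control replicate 2 and 4Gy_48h replicate 2, and 0.04 with RLE scaling (0.0496). With known genes alone pyroptosis, antioxidant and necroptosis genes did not pass (adjusted p = 0.208, 0.508 and 0.388), the medians of the last 2 being -0.05 and -0.08, and p53 targets (median -0.28, adjusted p = 6.71e-07), mitochondrially encoded genes (-0.28, 0.00396) and ribosomal protein genes (-0.11, 0.0393) fell. These falls were lost there with an estimated correlation (adjusted p = 0.206, 0.341 and 0.653). Over all genes p53 targets had 4 of 33 lower (median -0.12, adjusted p = 0.347). Ribosomal protein genes had a median of 0.04 with an adjusted p of 0.0939, and passed as higher without control replicate 3 (0.0163) or 4Gy_48h replicate 2 (0.0217).

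Not passed at 4Gy_48h were intrinsic apoptosis (adjusted p = 0.166), ferroptosis (0.286), homologous recombination (0.166), end joining (0.152), cholesterol synthesis (0.166), stress response (0.221), epithelial (0.166) and immune cell genes (0.65). G1/S genes (0.0807) passed as higher without control replicate 1 (0.00207) and 4Gy_48h replicates 1 and 3 (0.00971 and 0.0365). NF-kB genes (0.208) passed without control replicate 2 (0.0099), and mitochondrially encoded genes (0.482 over all genes) passed as lower without 4Gy_48h replicate 2 (0.00214). Endothelial genes had a test direction of higher (0.98) against a median of -0.13. In total 2649 genes passed, 684 higher and 1965 lower, of which 609 higher and 86 lower were known genes and 65 higher and 1834 lower were new loci. The number higher was 383 with only the 6 libraries compared, 420 with DESeq2 and 1185 without a filter. Known genes tested alone gave 130, 74 higher and 56 lower. The total was 1681 without control replicate 3, 1654 without 4Gy_48h replicate 1 and 1519 without 4Gy_48h replicate 2, with 412, 360 and 296 genes higher and 1269, 1294 and 1223 lower.

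The 48 h and 24 h libraries after 12 Gy were compared to follow the response over time at a fixed dose, and here no library was shared with the controls. Interferon-stimulated genes rose between the times: Ifit3 by 3.92, Rsad2 by 2.97 and Bst2 by 1.72. Tgtp1 rose by 4.41 and Cfb by 4.05. Zbp1 rose by 3.68 (adjusted p = 1.16e-07), from 5.31 ± 1.54 to 67.9 ± 10.0 CPM (SD, n = 3). Txnip rose by 3.36 (adjusted p = 3.24e-06) and Casp4 by 2.64 (adjusted p = 0.00186). The antigen presentation genes Tapbp, H2-K1 and Tap1 rose by 2.15, 1.53 and 1.49, the chemokine gene Ccl5 by 2.40, the chaperone genes Hspa5, Creld2 and Calr by 1.61, 1.01 and 0.93, and the p53 targets Mdm2, Ephx1 and Phlda3 by 1.14, 0.89 and 0.80. Over the same interval the glycolytic genes Ldha, Pgk1 and Eno1 fell by 1.05, 1.02 and 0.67, Tfrc by 1.99, Timp1 by 1.40 and Chac1 by 1.32. Falls also took in the cyclin gene Ccne2 (-1.07), the ribosomal protein genes Rpl7 and Rpl15 (-0.62 and -0.56), mt-Nd1 (-2.00), and the sparse genes Arsj, Flrt3 and Dhrs9 (-2.41, -2.26 and -2.23). Prss57 and Tmem86a were 53.8 times (95% counting interval 9.23 to 2170) and 32.7 times (5.45 to 1330) higher at 48 h, from 1 read each at 24 h. Casp1 (0.10, adjusted p = 0.668), Gsdmd (0.66, adjusted p = 0.282), Gsdme (-0.62, adjusted p = 0.076), Cdkn1a (0.04, adjusted p = 0.861) and Trp53 (0.07, adjusted p = 0.728) did not pass.

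Between 48 h and 24 h 9 lists differed. Interferon-stimulated genes were higher at 48 h, with 42 of 45 called by either adjustment (adjusted p = 1.39e-55), and only they kept the call with an estimated correlation (adjusted p = 0.0371). Class I presentation genes (11 of 17 higher, 14 over the list alone; adjusted p = 7.5e-09; adjusted p = 0.0995 with an estimated correlation) were higher too. P53 targets were higher, with 12 higher and 1 lower of 33 (14 and 1 over the list alone; adjusted p = 0.0258; adjusted p = 0.442 with an estimated correlation), a call lost without 12Gy_24h replicate 2 (0.0547), and their median of 0.47 was 0.29 without 12Gy_24h replicate 1. Nucleic acid sensing genes were higher, with 7 higher and 1 lower of 15 (7 and 2 over the list alone; adjusted p = 0.0403; adjusted p = 0.442 with an estimated correlation), but not with RLE (0.0566) or upper-quartile scaling (0.051), nor without 12Gy_24h replicates 1 and 2 (0.109 and 0.0547) or 12Gy_48h replicate 3 (0.0934). Ribosomal protein genes were lower at 48 h (1 higher and 18 lower of 30, 1 and 21 over the list alone; adjusted p = 2.11e-07; adjusted p = 0.275 with an estimated correlation). The 48 h libraries also had a longer read-weighted transcript length, 1080.7 ± 3.07 against 1038.0 ± 2.85 nt at 24 h (SD, n = 3), or 1252.6 ± 9.70 against 1203.4 ± 3.88 nt without ribosomal protein genes. Hypoxia and glycolysis genes (11 of 21 lower, 12 over the list alone; adjusted p = 3.35e-07; adjusted p = 0.139 with an estimated correlation) and G1/S genes (5 of 36 lower, 4 over the list alone; adjusted p = 0.000845; adjusted p = 0.451 with an estimated correlation) were lower. Ferroptosis genes had 2 higher and 6 lower of 19 (3 and 7 over the list alone; adjusted p = 0.00927; adjusted p = 0.357 with an estimated correlation; 0.107 with known genes alone). Their median of -0.27 was -0.41 without 12Gy_24h replicate 1 and -0.16 without 12Gy_48h replicate 1. Mitochondrially encoded genes had 5 of 12 lower (6 over the list alone; adjusted p = 0.00927; adjusted p = 0.442 with an estimated correlation), with a median of -0.46, or -0.29 without 12Gy_48h replicate 2.

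Not passed between the times were pyroptosis (3 higher and 1 lower, 3 and 0 over the list alone; adjusted p = 0.284, but 0.0233 with known genes alone), intrinsic apoptosis (0.166), end joining (0.342), NF-kB (0.505), cholesterol synthesis (0.177), epithelial (0.176), fibroblast (0.0986), immune cell (0.578) and stress response genes (0.288, but 0.00881 with known genes alone). In this comparison 10 lists passed with known genes alone, against 2 when the correlation was estimated as well. G2/M genes (0.2) and homologous recombination genes (0.0823) passed as lower without 12Gy_48h replicate 3 (0.0203 and 0.0334), and antioxidant genes (0.0986) without 12Gy_24h replicate 1 (0.0444). Necroptosis genes had a test direction of lower (0.982) with a mean of 0.24, YAP targets (0.196) a test direction of lower and a mean of -0.06 with a median of 0.00, and endothelial genes (0.819) a test direction of lower with a median of 0.01. In total 4825 genes passed, 3102 higher and 1723 lower. New loci gave 2069 higher and 124 lower, and known genes 978 higher and 1534 lower. With known genes alone 2329 passed, 1089 higher and 1240 lower. A fit to the 6 libraries alone gave 2857 higher and 2481 lower. Without 12Gy_24h replicate 2 there were 2065 higher, and without 12Gy_48h replicate 2 there were 1073 lower.

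The 12 Gy and 4 Gy libraries at 48 h were compared to ask what dose changed at a fixed time. The antioxidant genes Gsta1, Hmox1 and Gsta4 were higher after 12 Gy, by 2.96, 1.62 and 1.18. The interferon-stimulated genes Rsad2, Ifit3, Gbp2 and Oasl1 were higher by 1.36, 1.32, 1.21 and 0.81, and the chemokine gene Ccl5 by 1.46. Casp1 was higher after 12 Gy (27.2 ± 2.36 against 14.8 ± 1.57 CPM, SD, n = 3; log2 fold change 0.88, adjusted p = 0.0095). Gdf15 and Mdm2 were higher by 1.64 and 0.86. Ftl1, Sat1 and Pdia3 were higher by 0.65, 0.78 and 0.63, the lysosomal gene Cd68 by 1.48, and the cell cycle gene Cdca7 was lower by 0.94. Zbp1 (0.92, adjusted p = 0.0155) and Txnip (1.28, adjusted p = 0.022) were higher, but Zbp1 did not pass without 12Gy_48h replicates 2 and 3 (0.0678 and 0.0562), nor Txnip without 12Gy_48h replicates 1 and 2 (0.068 and 0.104) or 4Gy_48h replicates 1 and 2 (0.0561 and 0.0706). Gsdmd (-0.19, adjusted p = 0.832), Gsdme (-0.25, adjusted p = 0.628), Cdkn1a (0.19, adjusted p = 0.44) and Trp53 (0.21, adjusted p = 0.4) did not pass.

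Antioxidant genes also led the lists for dose, with 11 of 21 higher by either adjustment (adjusted p = 7.87e-14), and they alone kept the call with an estimated correlation (adjusted p = 0.0423), though not in the fit to known genes alone (0.0618). Interferon-stimulated genes were higher after 12 Gy (10 of 45, 13 over the list alone; adjusted p = 7.54e-11; adjusted p = 0.175 with an estimated correlation), as were class I presentation genes (4 of 17, 9 over the list alone; adjusted p = 5.35e-07; adjusted p = 0.0998 with an estimated correlation). P53 targets (5 of 33, 9 over the list alone; adjusted p = 3.02e-05; adjusted p = 0.175 with an estimated correlation) and ferroptosis genes (6 of 19, 7 higher and 2 lower over the list alone; adjusted p = 3.8e-05; adjusted p = 0.0998 with an estimated correlation) were higher. Stress response genes were higher (8 higher and 2 lower of 27, 13 and 4 over the list alone; adjusted p = 0.000111; adjusted p = 0.175 with an estimated correlation), with a median of 0.33, or 0.50 without 4Gy_48h replicate 1. Immune cell markers, 3 genes of which only Cd68 was called, were higher (adjusted p = 0.00751; adjusted p = 0.0998 with an estimated correlation), with a median of 0.91, or 0.60 without 12Gy_48h replicate 2. Ribosomal protein genes were lower after 12 Gy (3 of 30, 22 over the list alone; adjusted p = 1.29e-06; adjusted p = 0.175 with an estimated correlation). Read-weighted transcript length was 1080.7 ± 3.07 nt after 12 Gy against 1044.1 ± 10.5 nt after 4 Gy (SD, n = 3), or 1252.6 ± 9.70 against 1224.1 ± 10.6 nt without ribosomal protein genes. G1/S genes were lower (1 of 36; adjusted p = 0.000111; adjusted p = 0.476 with an estimated correlation), a call lost without 4Gy_48h replicate 2 (0.0907), with a median of -0.31 that was then -0.19. Hypoxia and glycolysis genes were lower (3 of 21, 6 over the list alone; adjusted p = 0.0157; adjusted p = 0.344 with an estimated correlation), lost without 4Gy_48h replicate 1 (0.142) or 12Gy_48h replicate 1 (0.0614).

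Not passed between doses were necroptosis (adjusted p = 0.231), end joining (0.41), epithelial (0.333), YAP (0.589) and fibroblast genes (0.589). Pyroptosis (0.0663) and nucleic acid sensing genes (0.0663) passed as higher without 12Gy_48h replicate 1 (0.0276 and 0.0177), and NF-kB genes (0.191) without 4Gy_48h replicate 1 (0.019). G2/M genes (0.135) passed as lower without 4Gy_48h replicate 3 (0.000999) or 12Gy_48h replicate 3 (0.000804), and homologous recombination genes (0.0663) without 4Gy_48h replicates 1 and 3 (0.0166 and 0.0172) or 12Gy_48h replicate 3 (0.0147). Endothelial genes (0.0519) passed with upper-quartile scaling (0.0496) and without 4Gy_48h replicate 3 (0.0456) or 12Gy_48h replicates 1 and 2 (0.0276 and 0.0238). Mitochondrially encoded genes (0.0793) passed as higher without 4Gy_48h replicate 2 (9.77e-07) or 12Gy_48h replicate 2 (0.00766). Intrinsic apoptosis (0.589) and cholesterol synthesis genes (0.616) had a test direction of higher and a mean of 0.06 each, against medians of -0.01 and -0.02. In total 707 genes passed, 331 higher and 376 lower, and with known genes alone 602 passed, 286 higher and 316 lower. The total was 442, 438 and 206 without 4Gy_48h replicates 1, 2 and 3, and 261, 76 and 393 without 12Gy_48h replicates 1, 2 and 3.

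Calls were shared between the comparisons with control in the same direction more often than independent calls would be. At 12Gy_48h and 4Gy_48h, which both raised Ifit3, Rsad2, Zbp1 and Aldoa, 450 genes were higher in both against 88.19 for independent calls, and 1695 were lower in both against 397.3. The 12 Gy groups at 24 h and 48 h, which both raised Nqo1, Hmox1 and Casp1, shared 872 higher genes against 360.7 and 2662 lower against 897.7. For 12Gy_24h and 4Gy_48h the counts were 441 against 126.9 and 1894 against 578.3. The products over all genes pool known genes, which gave most rises, with new loci, which gave most falls. Part of the excess over them follows from that mix, and no product was computed within the new loci. Known genes made up 392 of the 450, 817 of the 872 and 403 of the 441 shared rises. Independent calls among known genes would give 111.1, 474.5 and 161.4. Shared falls of known genes were 40, 85 and 48, against 3.218, 14.63 and 3.428. Scaling over all genes moved the known genes up. With known genes scaled and tested alone, 107, 424 and 69 genes were shared for these pairs, rises and falls together. The same controls enter all 3 comparisons and are too few to be split, so part of the excess follows from the sharing. In 20 simulations with no gene changed and shared simulated controls, a mean of 0, 0.05 and 0 genes was called in both comparisons of a pair. With nothing changed few calls are to be expected in any comparison. This count therefore does not show how much of the excess follows from the sharing. The covariance of the log2 fold changes across genes exceeded the simulated value by 0.728, 0.390 and 0.586 for the 12 Gy pair, the 48 h pair and the remaining pair, but genes are not independent replicates. Among known genes the excess was 0.0693, 0.0821 and 0.0624. There the correlations of the 12 Gy pair (0.403) and of 12Gy_24h with 4Gy_48h (0.468) lay below the simulated 0.496 and 0.486, and that of the 48 h pair (0.633) above 0.492.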

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

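Of the tests in this part, the receptor-read ratio at 24 h, the loci without a match and the leaving out of single libraries for interferon genes were written before their results were seen. The other tests of explanations and the fits to known genes alone were chosen after.

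Several responses differed between 24 h and 48 h after 12 Gy, by the direct comparison of those groups. Interferon-stimulated genes, class I presentation genes, nucleic acid sensing genes and p53 targets were higher at 48 h, with median log2 fold changes of 2.00, 0.99, 0.50 and 0.47. With an estimated correlation only interferon-stimulated genes kept the call (adjusted p = 0.0371), and the other 3 lists did not (0.0995, 0.442 and 0.442). Hypoxia and glycolysis, mitochondrially encoded, G1/S, ribosomal protein and ferroptosis genes were lower at 48 h, with medians of -0.58, -0.46, -0.34, -0.27 and -0.27. These 5 lost their calls with an estimated correlation (0.139, 0.442, 0.451, 0.275 and 0.357), and ferroptosis genes also with known genes alone (0.107). Reads at 48 h also lay on longer transcripts on average (1080.7 ± 3.07 against 1038.0 ± 2.85 nt, SD, n = 3), and RNA or library quality was not tested as a source of the ribosomal fall. The genes below were picked, after their values were seen, from those named by rule because they were called in opposite directions against control at the 2 times, so their difference between the times follows from that choice and is no further test. Dhx58, Psmb9, Usp18, Ifi44, Oas1g, H2-K1, Tap1 and Tap2 were higher at 48 h by 2.72, 2.52, 2.33, 2.16, 1.88, 1.53, 1.49 and 1.12, as were the chaperone gene Hspa5 (1.61) and Mdm2 (1.14). Timp1 and the replication regulator gene E2f8 were lower by 1.40 and 1.55 (log2 -1.40 and -1.55). The rise of Timp1 at 24 h over control (0.36, adjusted p = 0.0177) was lost without control replicate 2 (0.27, 0.0848) and with known genes alone (0.13, 0.503), and was 0.57 without control replicate 3, and the rise of Mdm2 at 48 h over control was lost with known genes alone (0.103). Prss57 had a fitted value of 5.15, which is no bound because it had 1 read at 24 h; the ratio of its reads was 53.8 (95% counting interval 9.23 to 2170). Among the lists, p53 targets lost their call without 12Gy_24h replicate 2 (adjusted p = 0.0547), and their median was 0.29 without 12Gy_24h replicate 1. Sensing genes lost theirs without 12Gy_24h replicates 1 and 2 and 12Gy_48h replicate 3 (0.109, 0.0547 and 0.0934) and with RLE or upper-quartile scaling (0.0566 and 0.051). The ferroptosis median was -0.41 without 12Gy_24h replicate 1 and -0.16 without 12Gy_48h replicate 1, and the mitochondrial median was -0.29 without 12Gy_48h replicate 2.

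Between 12 Gy and 4 Gy at 48 h, immune cell markers, antioxidant, class I presentation, interferon-stimulated, stress response, ferroptosis and p53 target genes were higher after 12 Gy, with medians of 0.91, 0.52, 0.48, 0.33, 0.33, 0.26 and 0.25. With an estimated correlation only antioxidant genes kept the call (adjusted p = 0.0423, but 0.0618 with known genes alone), and the other 6 stood at 0.0998, 0.0998, 0.175, 0.175, 0.0998 and 0.175. G1/S, ribosomal protein and hypoxia and glycolysis genes were lower, with medians of -0.31, -0.21 and -0.16, calls lost with an estimated correlation (0.476, 0.175 and 0.344). Here too the ribosomal fall went with longer transcripts (1080.7 ± 3.07 against 1044.1 ± 10.5 nt after 4 Gy). The immune cell median rests on 3 genes and was 0.60 without 12Gy_48h replicate 2. G1/S genes lost their call without 4Gy_48h replicate 2 (adjusted p = 0.0907), and hypoxia and glycolysis genes without 4Gy_48h replicate 1 and 12Gy_48h replicate 1 (0.142 and 0.0614). The stress response median was 0.50 without 4Gy_48h replicate 1.

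The first pattern weighed was the rise of interferon-stimulated genes, Zbp1 and Ifit3 among them, from 24 h to 48 h after 12 Gy. Scaling set by the new loci is argued against by the median of 2.044 with known genes alone, and a single deviant library by a lowest median of 1.861 (highest 2.079, highest adjusted p 1.42e-45) over the 6 libraries left out. Immune cells in the 12Gy_48h libraries would bring their other transcripts. Summed immune markers were higher in each of the 3 libraries at 12Gy_48h (47.4 to 56.6 CPM) than in any library of the other groups (at most 42), which left the question open, but from 24 h to 48 h all 20 markers together rose by 17.7 CPM (33.6 ± 7.61 to 51.3 ± 4.8, SD, n = 3), 15.5 of it from Cd68, against 4457 CPM for the interferon list (1727 ± 99.1 to 6183 ± 591). Of the 20 markers 9 had 0 reads at 12Gy_48h, among them Ptprc, Tyrobp and Fcer1g, which argues against such cells. A delayed interferon response to the dose is a candidate explanation, offered as a hypothesis, and time in culture without irradiation remains untested.

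The second pattern was the lower share of reads in new loci after irradiation, lowest at 12Gy_24h. Scaling does not enter this share, which differed by -9.09 percentage points between 12Gy_24h and control. Sharing of reads with near-identical known genes was first tested on the 235 loci without any match, whose median of -0.161 at 24 h was the value that explanation needs. The 123 loci with a strong protein match, tested later, had a median of 0.252 with 5.69% lower, which argues against it for those loci only. The 4540 other matched loci had a median of -1.945. A protein match does not measure how alike the reads are to a known gene, so sharing there was not tested and stays open. Transcripts with 1 of a few repeated sequences are a candidate source: 4087 loci whose best match is shared by at least 20 loci had a median of -1.984 (88.6% lower), against -0.127 for 378 loci whose match is shared by fewer than 5, but these groupings were chosen after looking at the annotation. Genomic DNA in the controls cannot be told apart from a true fall at 12Gy_24h. There reads in 1556 receptor genes (without Olfr889, whose counts had been seen) were 0.787 of control (95% interval 0.742 to 0.834). Without Olfr77, which held 38% of the receptor reads, the ratio was 0.816 (0.761 to 0.875), a fall smaller than the 0.568 of the new loci. At 12Gy_48h the ratio was 1.54, or 1.27 (1.19 to 1.35) without Olfr77, while the new loci's was 0.701. Receptor reads did not fall there, but a rise from another source could hide a fall in DNA reads, so genomic DNA is not excluded. At 4Gy_48h the ratio was 1.12 (1.07 to 1.19), or 0.961 (0.899 to 1.03) without Olfr77, against 0.751 for the new loci: no fall of receptor reads was seen, but a small one lies within the interval, which leaves it open.

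The third pattern was a set of 14 loci, with Sirt5 the only known gene, that were high in 8 of 9 irradiated libraries and low in the controls and in 4Gy_48h replicate 3. Of the 14, 11 had the same protein match in the deposited annotation, so they need not be separate observations. A control library under a wrong label is argued against by the interferon median of 1.07 in 4Gy_48h replicate 3, against -0.171 to 0.341 in the controls. Its total was 0.985 of the median of the other irradiated libraries, which argues against depth. A batch shared by the controls and this library is consistent with 166 other genes that part these 4 libraries from the remaining 8, against 11 and 10 with 4Gy_48h replicates 1 and 2 in its place; 165 of them were higher in the 4, and 3 were known genes. A smaller fall of the new loci in this library, which held 16.9% of its reads in them against 15.4% and 15.1% in 4Gy_48h replicates 1 and 2, would also give such a count and was not tested apart. The labels give no batch, but 1 that held all 3 controls would be confounded with every comparison with control. No biological explanation was tested.

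For the gene counts, 3 libraries against 3 make 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, gave a count as large: 4995 against a highest other of 0 for 12Gy_48h, 7238 against 24 for 12Gy_24h, 2649 against 0 for 4Gy_48h, 4825 against 1 for 48 h against 24 h, and 707 against 2 for 12 Gy against 4 Gy.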

How the results depend on the processing

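The fits to known genes alone were added after the data were seen, and the other alternatives were set beforehand. Over RLE and upper-quartile scaling, a mean of at least 5 CPM, DESeq2, only the 6 libraries compared and the replicate block, the totals of called genes were within 1.5 times those reported, but not all counts by direction were. Genes higher at 4Gy_48h numbered 383 with only the 6 libraries compared and 420 with DESeq2 against 684, and genes higher at 12Gy_48h 1281 with DESeq2 against 1945. With the replicate block the totals were 4713, 7096 and 2384 for 12Gy_48h, 12Gy_24h and 4Gy_48h against control, 4556 for 48 h against 24 h and 514 for 12 Gy against 4 Gy. Libraries with the same replicate number were no closer than others (mean correlation -0.015 against 0.007), so the numbers were not read as pairs.

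A fold of at least 2, a stricter threshold by construction, left 2524, 4517, 1412, 2397 and 222 genes in the same order, and 2080, 1102 and 1281 genes shared between 12Gy_48h and 12Gy_24h, 12Gy_48h and 4Gy_48h, and 12Gy_24h and 4Gy_48h. The fit to known genes alone tests fewer genes and sets scaling without the new loci: its counts were 1453, 1673, 130 and 2329 in the first 4 comparisons, and 424, 107 and 69 were shared. Without a filter 1113 genes passed for 12 Gy against 4 Gy, and genes higher numbered 4342 against 2798 at 12Gy_24h and 1185 against 684 at 4Gy_48h; the cause was not tested.

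Leaving out 1 library at a time gave 3803 to 4716 genes at 12Gy_48h, 6486 to 7260 at 12Gy_24h, 1519 to 2843 at 4Gy_48h, 3282 to 4579 for 48 h against 24 h and 76 to 442 for 12 Gy against 4 Gy. At 4Gy_48h the count moved by over 1.5 times without control replicate 3 (1681) and 4Gy_48h replicates 1 and 2 (1654 and 1519). For 12 Gy against 4 Gy each of the 6 libraries moved it so: 442, 438 and 206 without 4Gy_48h replicates 1, 2 and 3, and 261, 76 and 393 without 12Gy_48h replicates 1, 2 and 3.

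Of 24 gene lists tested, 11, 9, 10, 9 and 10 passed in the same order, counts that the replicate block left alike. With an estimated correlation, which differs for each list, 4, 0, 2, 1 and 1 passed by camera, against 8, 4, 7, 4 and 6 at an unadjusted p under 0.05. Known genes alone gave 7 at 12Gy_48h, and with an estimated correlation as well 1, 2, 3, 2 and 0, against 5 in each comparison at an unadjusted p under 0.05. Directional fry called 17 at 12Gy_48h and 15 at 12Gy_24h, and mixed fry 19, 22, 21 and 16 at 12Gy_48h, 12Gy_24h, 48 h against 24 h and 12 Gy against 4 Gy; fry tests a list by itself and not against other genes. At 12Gy_24h 4 to 10 lists passed with 1 library left out, 4 of them without control replicate 2. Among lists called in the reported fit or in the fit to known genes alone, the latter reversed the direction of the test for G2/M (-0.0221, with either correlation), class I presentation (-0.53) and ribosomal protein genes (-0.0913, with either correlation) at 12Gy_24h, and for ribosomal protein genes at 4Gy_48h (-0.1097). The medians of antioxidant and necroptosis genes at 4Gy_48h also changed sign (0.1023 to -0.0462 and 0.0692 to -0.0798), though the test still pointed up. Results of lists called in neither fit changed direction in 29 cases, or 31 with an estimated correlation. The cause was not tested beyond the change of scaling and comparison genes.

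No alternative reversed a called value of a named gene. For known genes alone, 370 of the values of named genes kept their direction and side of the threshold, 77 lost their call, 4 gained one and 10 uncalled ones changed sign. With DESeq2 418 kept both and 27 lost their call, and with the replicate block 441 and 18. Over all fits with 1 library left out, 2342 values kept both, 360 lost their call, 18 gained one and 46 uncalled ones changed sign. On simulated counts at this depth, with a small set of changed genes, the gene test recovered 13.5% of 1.5-fold and 50.2% of 2-fold changes at 12Gy_48h. Changes of that size can thus go uncalled, but recovery in the data, where many more genes were called, may differ.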

Other observations

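The pathway tests and the genes in this part were chosen after the results were seen. Of 277 pathways in the deposited annotation, tested with known genes alone and limma camera at the preset correlation, 103 passed at 12Gy_48h, 10 at 12Gy_24h and 25 at 4Gy_48h against control, and 52 each for 48 h against 24 h and 12 Gy against 4 Gy. With an estimated correlation camera passed 0 in each of the 5 comparisons, against 86, 28, 30, 48 and 57 at an unadjusted p under 0.05; no other tool was run on pathways.

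Ribosome genes were lower at 12Gy_48h (median -0.320, 80 of 139 called lower and 3 higher, adjusted p = 4.58e-20, 0.106 with an estimated correlation) and lower after 12 Gy than after 4 Gy (-0.246, 36 lower, adjusted p = 1.57e-17, 0.205 with an estimated correlation). Oxidative phosphorylation genes were lower at 12Gy_48h (-0.202, 35 of 120 called lower and 1 higher, adjusted p = 7.8e-06, 0.186 with an estimated correlation). The 12Gy_48h libraries also stood apart in read-weighted transcript length (1077.5 to 1083.6 nt against at most 1056 nt in the other groups) and in the share of reads in genes over 3000 nt (3.94 to 4.06% against at most 3.77%). The fall of ribosomal protein genes enters this length: without them it was 1241.6 to 1259.8 nt against at most 1245.7 nt in the other groups. A difference in RNA or library quality was not tested as a source of these falls of ribosome and oxidative phosphorylation genes. At 12Gy_24h glycolysis genes were higher (0.280, 20 of 48 called higher and 1 lower, adjusted p = 1.04e-05, 0.379 with an estimated correlation). Folate one-carbon genes were lower after 12 Gy than after 4 Gy (-0.471, 6 of 16 called lower, adjusted p = 4.72e-05, 0.101 with an estimated correlation). Mthfd1 and Shmt1 were lower at 12Gy_48h than in the controls by edgeR (-0.56 and -0.52, adjusted p = 0.00756 and 0.0406). Ctsl, a lysosomal protease gene, was higher in the comparisons of 12Gy_48h, 12Gy_24h and 4Gy_48h with control (0.83, 1.32 and 0.69).

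Of 29 intestinal lineage markers 19 had reads in some library, and none reached the level needed for testing.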
